A study of Mus musculus with 12 samples.

How the data were processed

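RNA was measured in 12 libraries of mouse pancreatic tumour organoids, from 2 lines and 3 conditions with 2 libraries per group. Per the labels, RNA was extracted with Trizol, treated with DNase and made into strand-specific libraries with a TruSeq Stranded Total RNA kit. The authors checked reads with FastQC 0.11.8, aligned them with STAR 2.5.2b to GRCm38.p6 and quantified them with RSEM 1.3.0. The deposited values are expected counts and TPM (transcript abundance scaled to a fixed total) per gene, and each test here used expected counts rounded to whole numbers unless TPM is named. Between 8.08% and 11.3% of the expected counts were not whole within a tolerance of 0.005. The labels do not say whether the libraries of a group are separate cultures, so p-values measure only the spread between these libraries.

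The 53715 gene identifiers were matched to GENCODE M21, 53620 without regard to version and 51464 with the same version. The 95 without a symbol held 0.011% of the counts. Depth ran from 9094295 to 28903831 counts per library, a ratio of 3.18. Intervals and floors cover counting error only. The floor is 3 counts summed over a group, equal to 0.107 to 0.352 CPM in a single library. A fold against a group at 0 is given as a lower bound against that floor, and a group at 1 to 3 counts gets the ratio of summed counts with a 95% exact interval. No fold is given where both groups lie at or under the floor. CPM are scaled by TMM factors, which ran from 0.839 to 1.20.

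Genes were filtered with filterByExpr by group, leaving 14473, and fitted with edgeR 4.0.16 (robust quasi-likelihood, a group mean for each of the 6 groups, 6 residual degrees of freedom, biological coefficient of variation 19.2%). Comparisons were contrasts of that fit: knockout against control, libraries labelled re-expression against knockout, and these against control, each averaged over the lines. The first pair was also read in each line, with the difference between lines, and the controls of the lines were compared. Adjusted p are Benjamini-Hochberg values with a threshold of 0.05, two-sided. Camera in limma 3.58.1 tested the lists with a preset correlation of 0.01 between genes and with an estimated one, and fry tested them on the same values. No list passed with an estimated correlation. DESeq2 1.42.0, R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and the data.table package (version 1.17.8) were also used.

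The groups, comparisons, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule names 12 genes outright (Spdef, Agr2, Ern2, Muc5ac, Muc1, Muc6, Tff1, Tff2, Gata6, Krt17, Hspa5 and Dnajb9). It adds the 10 largest rises and falls in each of the first pair of comparisons, among genes past the threshold with a mean of at least 1 CPM, the same direction in both lines and no overlap between the groups of either line. It adds 5 of each for re-expression against control, 3 of each for a single line and for the controls, the 5 smallest adjusted p for each difference between lines, 10 shared genes changed oppositely, and up to 3 members of each list. Predicted genes, pseudogenes and genes without a symbol are left out. A few genes that the rule or the lists name are not reported here. There are 26 lists: mucins and trefoil factors, mucin O-glycosylation enzymes, goblet cell maturation, IRE1-XBP1, ATF6 and PERK-ATF4 targets, transport from endoplasmic reticulum to Golgi, classical and basal-like subtypes, epithelial-mesenchymal transition, proliferation, cholesterol synthesis, interferon response, hypoxia and glycolysis, MAPK output, Wnt targets, p53 targets, gastric cells, ductal and progenitor markers, acinar markers, tuft and enteroendocrine markers, fibroblast, immune and endothelial markers, immediate early and heat shock genes, mitochondrially encoded genes, ribosomal protein genes and replication-dependent histone genes. They share members, Foxa3 and Rap1gap among them. The pattern for ribosomal protein genes also took in kinase genes such as Rps6ka2. Acinar markers had 1 measured member and were not tested, which left 75 tests adjusted together. Called members are counted out of the measured ones, those left by the count filter, and not out of the whole list. Measured were 18 of 36 epithelial-mesenchymal transition genes, 28 of 43 basal-like and 40 of 50 classical markers. For goblet genes it was 22 of 32, and for tuft and enteroendocrine markers 4 of 30. By fry's test of direction, goblet, classical and epithelial-mesenchymal transition genes passed in the knockout (adjusted p = 0.0213, 0.0213 and 0.0391). Goblet and O-glycosylation genes passed fry in re-expression against knockout (0.00139 each). Against control these passed (0.00551 and 0.00201), with epithelial-mesenchymal transition (0.0241). No other list passed fry, including interferon genes in the knockout (0.446).

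Libraries with the same replicate number resembled each other across groups: the residuals correlated in all 15 pairs of groups, from 0.205 to 0.531, above the 0.1 set for treating them as paired. Values with the replicate number as a block are therefore given beside the numbers of genes and some of the other results that it moved. Replicates of a group had chi-square values per degree of freedom of 32.3 to 90.0, and Pearson correlations of log CPM across genes of 0.961 to 0.982. Ribosomal RNA gene CT010467.1 took 5.48% to 14.4% of the counts.

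The steps were tested on simulated data with 14139 genes. Of genes changed 2-fold and 4-fold, 61.9% and 78.9% were recovered in the averaged knockout comparison, with 7 false among 142 calls, and 59.8% and 82.1% in re-expression against knockout, with 7 among 143. In single lines 36.1% and 73.7% (mT6) and 36.1% and 69.5% (mT69a) were recovered, with 10 false among 115 and 9 among 110. The difference between lines, simulated at 0, gave no call in edgeR, the only tool run there. A list lowered by 0.6 on the log2 scale was recovered, and none of the 24 others was called by camera. Genes were drawn independently there, so this cannot show how often camera calls lists whose members vary together. In the data the correlations estimated for the knockout comparison ran from -0.094 (tuft and enteroendocrine markers) to 0.777 (mitochondrially encoded genes). Alternatives were DESeq2's size factors, no count filter, DESeq2's Wald test, limma on log2(TPM + 1) and log2(TPM + 0.1), the same without a filter on TPM, the replicate block, the block within each line, only the groups compared, each library left out and the estimated correlation. After the data were seen, fits without mitochondrial and ribosomal RNA genes and fits of either replicate number alone were added.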

Results

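Total RNA was sequenced from organoids of mouse pancreatic ductal adenocarcinoma, epithelial cultures grown in Matrigel. The organoids came from 2 lines, mT6 and mT69a. Each line was studied as a Rosa26-knockout clone with an empty vector (the control), as an Spdef-knockout clone with an empty vector, and as the same kind of knockout clone with an SPDEF vector, here called re-expression as labelled. SPDEF is an ETS-family transcription factor of mucus-secreting epithelial cells. There were 2 libraries in each of the 6 groups and 12 in all, holding 9094295 to 28903831 expected counts each. Mitochondrial genes took 12.7% to 15.5% of the counts in the libraries numbered 1 and 18.6% to 27.1% in those numbered 2, whatever the condition. The first component of the expression values held 44.8% of the variance and separated the lines.

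The targeted gene was read first in every library. Spdef (ENSMUSG00000024215, chromosome 17, 27714352 to 27728955 on GRCm38) had 30 and 29 counts in the 2 mT6 control libraries, 0 and 2 in the mT6 knockout libraries, and 1 and 0 in the mT6 libraries labelled re-expression. In mT69a it had 2 and 4 counts in the controls, 2 and 0 in the knockout libraries, and 2 and 0 in those labelled re-expression. The summed counts were 22.7-fold lower in the mT6 knockout than in its control (95% counting interval 6.01 to 192). The mT69a control already lay near the floor, so its ratio of 2.93 (0.52 to 29.7) shows no loss at this depth. Averaged over the lines, the fall missed the threshold in edgeR's quasi-likelihood test (adjusted p = 0.0793), and passed it with the replicate number as a block (0.0258). Since mouse Spdef was at the floor in all 4 libraries labelled re-expression, directions drawn from them rest on that label, and they are named as labelled throughout.

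The first comparison asks what differed between the Spdef knockout and the control. Each line had 1 knockout clone, so effects of the loss and of the clone cannot be told apart within a line. Agr2, a protein disulfide isomerase of the endoplasmic reticulum needed for mucin folding, fell from 99.2 ± 12.3 to 18.3 ± 8.36 CPM (counts scaled to library size, mean ± SD, n = 2) in mT6 and from 12.8 ± 9.43 to 0.335 ± 0.018 in mT69a. Its averaged log2 fold change was -3.82 ± 0.53 (SE, 4 libraries against 4, adjusted p = 0.00398). Ern2, the IRE1 paralog of mucus-secreting epithelium, was 2.46-fold lower in mT6 (counting interval 2.05 to 2.98) and 50.7-fold lower in mT69a (13.7 to 425; adjusted p = 0.00273). Creb3l1, a membrane-bound transcription factor of secretory cells, was 10.2-fold (6.76 to 15.9) and 9.76-fold (3.03 to 49.97) lower (adjusted p = 0.000143). Foxa3, a forkhead factor of goblet cells, fell by 2.55 on the log2 scale (SE 0.19, adjusted p = 4.11e-05).

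Among the other largest falls, the lipid transfer protein gene Gramd1b fell by 3.86 on the log2 scale (SE 0.42, adjusted p = 0.000703). Pik3c2g, a class II phosphoinositide kinase gene, was 21.5-fold lower in mT6 (7.12 to 107) and 10.7-fold lower in mT69a (adjusted p = 0.00781). Trf (transferrin), Cachd1, Khdc1a, Nepn and Gata5 completed the set, with adjusted p of 0.00233, 0.00446, 0.00806, 0.0393 and 0.0307. Cachd1 was 74.5-fold lower in mT69a (25.2 to 364) and at least 4.61-fold lower in mT6, where the knockout had 0 counts against 18. Trf was 29.4-fold lower in mT6 and Khdc1a 49.3-fold, each from low mT69a levels of 12 and 5 counts in the control. Gata5, an endodermal GATA factor, was 11.5-fold lower in mT69a (8.72 to 15.3), with only 3 counts in the mT6 controls.

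Of the largest rises, Prex2, a Rac exchange factor gene, rose by 4.14 on the log2 scale (SE 0.52, adjusted p = 0.00153). Gnai1, Runx3 and Plcb1 rose 1.88-, 1.45- and 2.02-fold in mT6 and at least 46.1-, 23.6- and 5.47-fold in mT69a. Igfbp3, a secreted binder of insulin-like growth factors, rose at least 15.2-fold in mT6 and 2.89-fold in mT69a. Lipo3 and the interferon-inducible genes Ifi211, Ifi204 and Cmpk2 also rose, 178-fold (49.0 to 1478), 237-fold (65.2 to 1961), 738-fold (132 to 29184) and 82.3-fold (27.8 to 402) in mT69a against 2.66-, 6.28-, 2.23- and 2.40-fold in mT6. The interferon-inducible genes were higher in the first mT69a knockout library than in the second, with 395, 631 and 233 counts against 67, 89 and 8. Without that first library their folds were 89.9 (23.9 to 757), 239 (41.8 to 9536) and 7.15 (1.72 to 41.9). Ifi211, Ifi204, Lipo3 and Khdc1a belong to families of near-identical copies, so their counts are uncertain. Genes of chromosomes 1 and 19 had median log2 fold changes of -0.28 and -0.29 in mT6, which bears on Prex2, Ifi211, Ifi204, Khdc1a and Lipo3. Genes of chromosome 12 had a median of -0.34 in mT69a, which bears on Agr2 and Cmpk2.

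With single libraries left out, Cmpk2 lost its call in 11 of 12 fits, Gata5 in 8 and Nepn in 7. Their highest adjusted p were 0.159 without the first mT69a control, 0.183 without the second mT6 control and 0.153 without the first mT69a knockout library. Plcb1 was lost without the first mT69a control or the first mT69a knockout library (up to 0.0636), Ifi204 without the second mT6 knockout library (0.0552) and Khdc1a without the second mT69a control (0.0801). Cmpk2 also missed the threshold under the replicate block (0.0627). Of 14473 genes tested, 477 were higher and 333 lower in the knockout on the average of the lines. Of these, 265 and 138 changed by more than 2-fold, and 81 of the 810 had a group at 3 counts or fewer. Such a call does not require a change in both lines. Read by line, 41 genes rose and 29 fell in both, while 50 fell in mT6 and rose in mT69a and 15 did the reverse. The log2 fold changes of the lines had a Pearson correlation of 0.00614 across genes. A fit of these groups alone, with line as a term and the difference between lines not fitted, called 108 genes. The replicate block raised the averaged number from 810 to 2171, with 1152 higher and 1019 lower. It fell to 512 without the first mT6 knockout library, 528 without the second mT6 control, 502 and 494 without the first or second mT69a control, and 431 without the first mT69a knockout library.

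Genes of goblet cell maturation fell with the knockout, 8 of 22 measured members, with the other 14 not past the threshold and 8 falling when adjusted over the list alone. Creb3l1, Foxa3 and Rap1gap led it, the last by 1.5 on the log2 scale (SE 0.11, adjusted p = 4.25e-05). The list's median was -0.86, or -0.80 with genes near 0 counts set at their bound (camera adjusted p = 4.35e-06; adjusted p = 0.545 with an estimated correlation). Of 40 markers of the classical subtype of pancreatic cancer, 9 fell and 3 rose (13 and 3 adjusted over the list alone), with a median of -0.46, or -0.34 at the bounds (camera adjusted p = 1.83e-05; adjusted p = 0.466 with an estimated correlation). In mT69a 17 fell and 1 rose, with a median of -0.66, and in mT6 2 fell, with -0.02. Foxa3 and Rap1gap are in this list too, while its member Atp10b, a lipid flippase gene, rose by 1.22 ± 0.17. Of 11 mucins and trefoil factors, Muc20 and Muc13 rose by 1.06 ± 0.19 and 0.91 ± 0.23, and 2 rose when adjusted over the list alone. Muc4 missed the threshold (1.07, adjusted p = 0.142) and passed it under the replicate block (1.15, adjusted p = 0.00370). Camera gave an upward direction (adjusted p = 0.771) against a median of -0.46 and a mean of -0.08. The lines went opposite ways for Muc20, by -1.70 in mT6 and 3.82 in mT69a (adjusted p of the difference 2.62e-05), and fits of either replicate number alone, which weight the lines by their counts, turned it to -0.02 and -0.26. Muc20 lost its call without the first mT69a control (0.0537), and Muc13 in 9 of 12 fits (up to 0.174 without the first mT69a knockout library) and under the block (0.0599).

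Of 26 mucin O-glycosylation enzymes, 2 fell, 1 rose and 23 did not pass (5 and 2 adjusted over the list alone; camera adjusted p = 0.696). Gcnt3, a core mucin branching enzyme gene, fell by 0.67 on the log2 scale (SE 0.10). Galnt6, which starts mucin glycosylation, had 32 counts in the mT69a controls and 0 in the knockout, at least 10.4-fold lower, while in mT6 it was 1.53-fold higher (0.98 to 2.41), and its averaged fall lost its call without the first mT69a knockout library (0.0741). Among 35 targets of the IRE1-XBP1 stress pathway 1 fell (camera adjusted p = 0.225), and no member passed when adjusted over the list alone, with 4 at an unadjusted p under 0.05. That member, Ern1, lost its call in 8 of 12 fits (up to 0.134 without the first mT6 knockout library). Among 22 chaperones of the ATF6 arm and 40 genes of transport between endoplasmic reticulum and Golgi, no member passed edgeR's test, over all genes or over the lists alone. At an unadjusted p under 0.05 there were 6 and 8, and DESeq2 called 0 and 1. Under the replicate block 1 chaperone gene was lower, and of the transport genes 7 were lower and 1 higher, with Copa and Sec16b falling by 0.28 and 0.76 on the log2 scale and Copg2 rising by 0.25 (adjusted p = 0.00877, 0.0159 and 0.0445). The block gave 5 lower and 3 higher O-glycosylation enzymes and 2 lower and 1 higher IRE1-XBP1 targets. Of 32 PERK-ATF4 targets Nupr1 alone passed in edgeR, rising by 0.89 ± 0.11 (adjusted p = 0.000979; 1 adjusted over the list alone; camera adjusted p = 0.975), while DESeq2 called 2 and the block 2 higher and 3 lower. The chaperone genes Hspa5 and Dnajb9, read individually, gave 0.17 ± 0.14 and -0.17 ± 0.14 (adjusted p = 0.586 and 0.586). Muc1, Muc5ac, Muc6, Tff1 and Tff2 gave 0.08, -0.46, -0.84, -0.54 and -1.05 on the log2 scale and did not pass (adjusted p = 0.728, 0.670, 0.650, 0.601 and 0.328). By line, Muc5ac gave 1.31 in mT6 and -2.23 in mT69a and passed in neither (adjusted p = 0.285 and 0.0940, and 0.0514 for the difference). Tff2 fell by 2.98 in mT6 (adjusted p = 0.0363) and did not pass in mT69a (0.655, and 0.0551 for the difference).

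Of 18 genes of epithelial-mesenchymal transition, 4 rose and 14 did not pass (7 rose and 1 fell adjusted over the list alone). In mT69a 9 rose and 1 fell, with a median of 1.74, and in mT6 2 rose and 2 fell, with -0.09. Timp3, an inhibitor of matrix proteases, rose by 3.16 ± 0.27, and the basement membrane collagens Col4a1 and Col4a2 by 1.10 ± 0.14 and 1.25 ± 0.20, all 3 differing between the lines (adjusted p = 3.35e-05, 0.00179 and 0.00517). The collagens belong to basement membranes of epithelia as well. The median was 0.92, or 0.63 with genes near 0 counts set at their bound (camera adjusted p = 0.00062; adjusted p = 0.539 with an estimated correlation). The list missed the threshold in the fits on log2(TPM + 1), on log2(TPM + 0.1) and without a filter on TPM (0.0823, 0.0604 and 0.0694). Of 42 interferon response genes 5 rose, with 19 rising and 1 falling when adjusted over the list alone, and a median of 1.65, or 1.54 at the bounds (camera adjusted p = 2.29e-06; adjusted p = 0.901 with an estimated correlation). The rise was in mT69a, with 22 genes and a median of 3.65, or 6 and 1.02 without the first mT69a knockout library and 2 without either mT69a control, while in mT6 none rose in edgeR (4 at an unadjusted p under 0.05) and 1 fell, with a median of -0.16. Averaged over the lines, DESeq2 called 18 of the 42 genes, and the block gave 3 higher and 1 lower. Tap1 and Parp14 rose by 1.59 ± 0.30 and 1.69 ± 0.38 on average. Tap1 lost its call without the first mT69a control (0.0661), and Parp14 in 10 of 12 fits (up to 0.136, also without the first mT69a control) and under the block (0.0758). Of 28 basal-like subtype markers, 2 rose and 1 fell (5 and 1 adjusted over the list alone; median 0.42, or 0.33 at the bounds; camera adjusted p = 0.00954; adjusted p = 0.901 with an estimated correlation). The block gave 7 higher and 1 lower. Ly6d and Il1rn rose by 1.76 and 0.92. Ly6d lost its call without the second mT6 control or the first mT69a control or knockout library, up to 0.0696 without the first of these. Il1rn lost its call in 4 fits, up to 0.0669 without the second mT69a control.

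**Figure D1:**
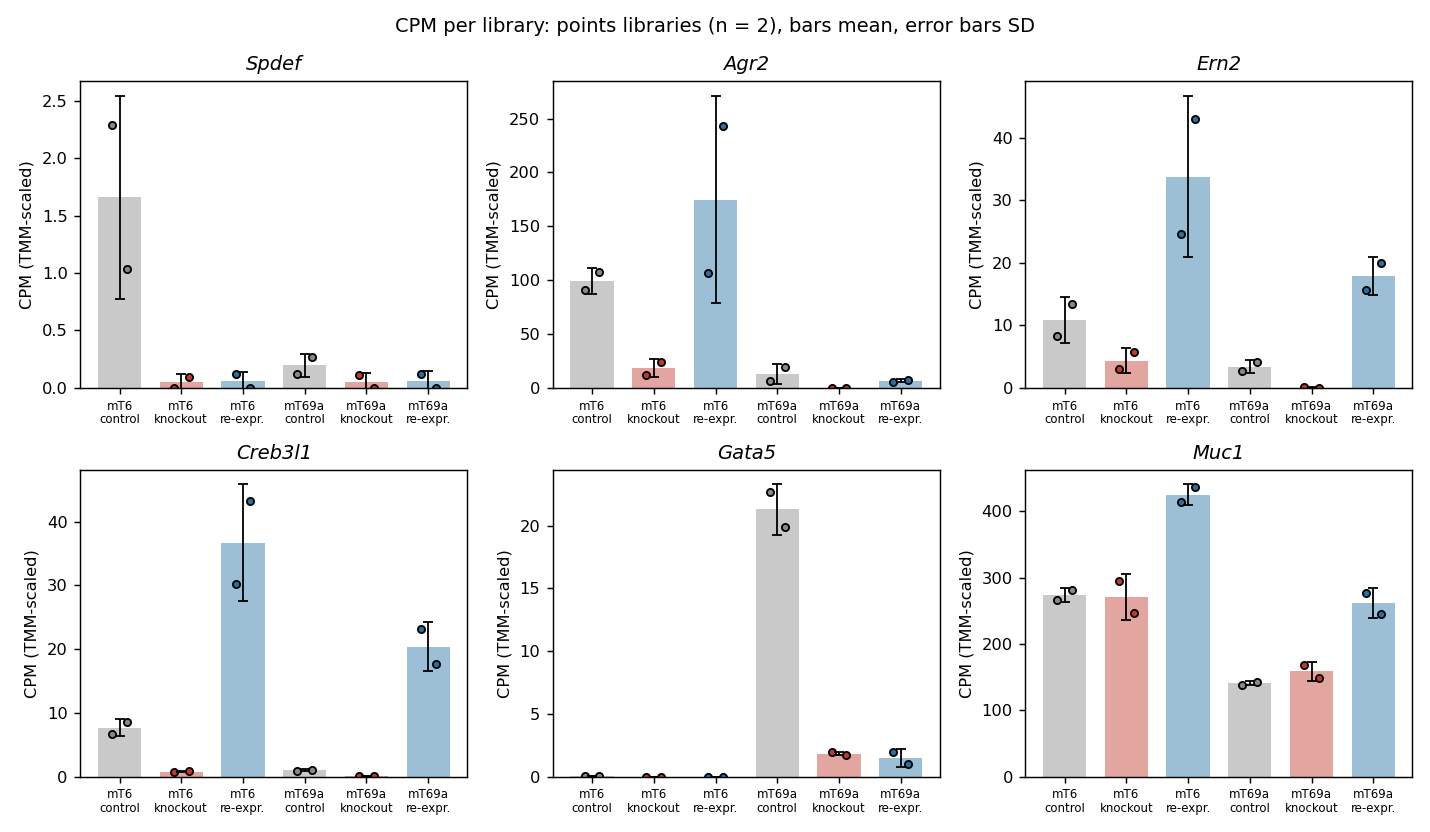
CPM (counts scaled to library size) of Spdef, Agr2, Ern2, Creb3l1, Gata5 and Muc1 in each library, by line and condition; points are libraries and bars are group means. Agr2 averaged 99.2 in the mT6 controls, 18.3 in the knockout and 175 in the libraries labelled re-expression, while Spdef stayed at or near 0 in the last.

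The next comparison asks what changed when the SPDEF vector was added to the knockout clones, as labelled. Creb3l4 and Creb3l1, related membrane-bound transcription factors of secretory cells, rose in both lines. Creb3l4 went from 1.60 ± 0.384 to 81.3 ± 4.82 CPM in mT6 and from 0.848 ± 0.093 to 67.3 ± 1.92 in mT69a (log2 fold change 5.95 ± 0.14, adjusted p = 6.85e-09). Creb3l1 rose 46.5-fold (31.2 to 72.3) and 210-fold (71.7 to 1023; adjusted p = 3.88e-07). Agr2 rose to 175 ± 96.4 and 6.61 ± 1.37 CPM (3.75 ± 0.54, adjusted p = 0.00347), and Ern2 rose 7.08-fold and 262-fold (72.2 to 2172; adjusted p = 5.47e-05). Muc1, a transmembrane mucin gene, rose from 271 ± 34.6 to 425 ± 15.8 CPM in mT6 and from 159 ± 14 to 261 ± 22.7 in mT69a (0.68 ± 0.09, adjusted p = 0.00129).

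Gkn3, a gastrokine gene of mucus cells of the stomach, had 0 counts in every knockout library and was at least 56.8-fold higher in mT6 and 120-fold higher in mT69a (adjusted p = 9.16e-05). Spats2l rose by 7.24 ± 0.30 on the log2 scale (adjusted p = 1.18e-06). Slc12a8, Plac9a, Lman1l and Adamtsl3 rose at least 95.7-, 20.4-, 67.3- and 4.32-fold in mT6, and Psors1c2 101-fold (27.3 to 844). In mT69a Slc12a8 rose 21.6-fold (7.03 to 107), Psors1c2 284-fold (78.2 to 2350), Plac9a 17.1-fold, Lman1l 15.6-fold (3.95 to 135) and Adamtsl3 at least 39.5-fold. The falls included Psca, a surface antigen of gastric and prostate epithelium, by 3.93 on the log2 scale (SE 0.31, adjusted p = 4.41e-05), the matrix glycoprotein gene Fbln1 by 3.68 (SE 0.31) and the platelet chemokine gene Ppbp by 4.36 (SE 0.44). The neighbouring genes Ptpn22, a lymphoid phosphatase, and Bcl2l15, of the BCL2 family, fell by 3.66 (SE 0.25) and 3.48 (SE 0.30). Adgrg7, Cdhr2 and Lypd2 fell 47.5-fold (12.96 to 395), 14.3-fold (3.77 to 121) and 4.36-fold in mT6 and 4.54-, 9.77- and 28.8-fold (the last 7.64 to 243) in mT69a. Efcab3 and Gsdmc2 fell 14.2-fold and 156-fold (27.6 to 6195) in mT69a from 107 and 168 counts. Efcab3 was at least 1.08-fold lower in mT6, and Gsdmc2, a member of a gene cluster with near-identical copies, had too few counts there to give a fold. Without the second mT6 knockout library Efcab3 and Cdhr2 missed the threshold (0.0597 and 0.0662), and Gsdmc2 did so without the first mT6 knockout (0.148) or the first mT69a re-expression library.

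In all, 645 genes were higher and 480 lower in the libraries labelled re-expression, 301 and 218 of them by more than 2-fold, and 75 of the 1125 had a group at 3 counts or fewer. The replicate block gave 2293 (1209 higher, 1084 lower). On log2(TPM + 0.1), where the median of all genes was -0.13, the split was 196 higher against 225 lower. The number fell to 696 and 748 without the first or second mT69a knockout library, and to 637 and 711 without the first or second mT69a library labelled re-expression.

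Goblet cell maturation genes rose as a group in the libraries labelled re-expression, 12 of 22, with 1 falling (13 and 2 adjusted over the list alone). The median was 1.3, or 1.26 at the bounds (camera adjusted p = 8.32e-09; adjusted p = 0.457 with an estimated correlation), and Rap1gap, one of its members, rose by 2.52 ± 0.11. Of 26 mucin O-glycosylation enzymes 8 rose and 1 fell (13 and 2 adjusted over the list alone; median 0.43; camera adjusted p = 1.36e-06; adjusted p = 0.429 with an estimated correlation). Galnt12, a starter of O-glycan chains, rose by 2.56 ± 0.15, and the sialyltransferase genes St3gal4 and St6galnac2 by 1.28 ± 0.09 and 4.44 ± 0.33. Mucins and trefoil factors split, 1 rising and 4 falling of 11 (2 and 4 adjusted over the list alone), with camera downward (adjusted p = 0.771), a mean of -0.10 and a median of 0.43. Read by line, 3 members rose and 1 fell in mT6 (median -0.32). In mT69a 1 rose (median 0.27). Averaged over the lines, Muc20 and Muc4 fell by 1.29 and 1.93 on the log2 scale, and Tff1, a trefoil factor gene of gastric surface cells, by 2.5 (SE 0.54, adjusted p = 0.0245). Tff2 had 14 counts in the mT6 knockout against 2, 3.78-fold lower (0.87 to 34.3), and 11 in the mT69a knockout against 0, at least 3.40-fold lower (adjusted p = 0.0373). Tff1, Tff2 and Muc4 lost their calls in 7, 9 and 4 of 12 fits with 1 library left out. Their highest adjusted p were 0.117 without the second mT6 re-expression library, 0.139 without the second mT6 knockout and 0.0600 without the first mT69a re-expression library. Muc5ac, the gel-forming mucin gene of surface cells, missed the threshold (-1.08 ± 0.52, adjusted p = 0.304) and passed it under the replicate block (0.00616), and Muc6 gave 0.91 ± 0.81 (adjusted p = 0.634).

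Genes of the secretory pathway rose in smaller numbers. Of 35 IRE1-XBP1 targets 5 rose (6 adjusted over the list alone), among them Edem1, which feeds misfolded proteins to degradation, by 0.67 ± 0.10, Sec11c by 0.70 ± 0.13 and Pdia5 by 1.13 ± 0.23 (list camera adjusted p = 0.00177). Of 22 ATF6-arm chaperones 3 rose (4 adjusted over the list alone), Txndc11, Fkbp11 and Dnajc10, by 0.74 ± 0.12, 0.90 ± 0.15 and 1.3 ± 0.21 (camera adjusted p = 0.0264). Of 40 transport genes 3 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.00468), with Kdelr3 and Sec24a up by 0.98 and 0.51 and Sec16b down by 2.81 on the log2 scale. For each of these lists the adjusted p = 0.901 with an estimated correlation. The block gave 10 higher IRE1-XBP1 targets, 6 higher chaperone genes, and 11 higher and 2 lower transport genes. By camera the transport list missed the threshold in the 3 fits on TPM (0.0563, 0.0604 and 0.112), as did the ATF6 list (0.0563, 0.0604 and 0.138). The ATF6 list also missed it without a count filter (0.0748), and the IRE1-XBP1 list without a filter on TPM (0.0856). Without the second mT6 re-expression library the IRE1-XBP1 and ATF6 lists missed the threshold (0.185 and 0.422). The ATF6 list did so as well without the second mT69a re-expression library (0.154) and without the first mT6 knockout (0.0849). Pdia5 and Sec24a lost their calls without the first mT69a knockout (0.0653 and 0.0663) or the first mT69a re-expression library, and Kdelr3 without the second mT69a knockout (0.0503). Hspa5 and Dnajb9 gave -0.01 ± 0.14 and 0.00 ± 0.11 (adjusted p = 0.993 and 0.9999).

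Among 40 classical subtype markers 5 rose and 9 fell (6 and 11 adjusted over the list alone; camera adjusted p = 0.381), Foxa3 and Fxyd3 rising by 4.10 ± 0.19 and 2.25 ± 0.10. Of 28 basal-like markers 6 fell and 2 rose (9 and 3 adjusted over the list alone; median -0.29; camera adjusted p = 0.0264; adjusted p = 0.901 with an estimated correlation). Anxa8, Il1rn and the chromatin factor gene Hmga2 fell by 1.68, 1.48 and 1.03 on the log2 scale. The block gave 12 lower and 3 higher basal-like markers, and camera missed the threshold in the 3 fits on TPM (0.138, 0.152 and 0.0616). That list missed the threshold without the first mT6 knockout (0.0767) or the second mT6 re-expression library (0.143). Of 18 genes of epithelial-mesenchymal transition 3 rose (3 adjusted over the list alone), while the median was -0.26 (camera downward, adjusted p = 0.719). Among them were Itga5 and Tpm1, the latter by 0.60 ± 0.15. Tpm1 lost its call in 8 of 12 fits (up to 0.149 without the second mT69a knockout). Of 42 interferon response genes 1 rose (camera adjusted p = 0.764; median -0.45), Iigp1, which lost its call in 10 fits (up to 0.167 without the first mT69a re-expression library). None passed over the list alone or in DESeq2, with 3 at an unadjusted p under 0.05, and the block gave 2 higher and 1 lower. The interferon list turned upward without the first mT69a knockout library (5.80e-06) and downward without the second (6.75e-09). Krt17, a basal keratin gene, had 0 or 1 count in every library and was not tested.

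**Figure D2:**
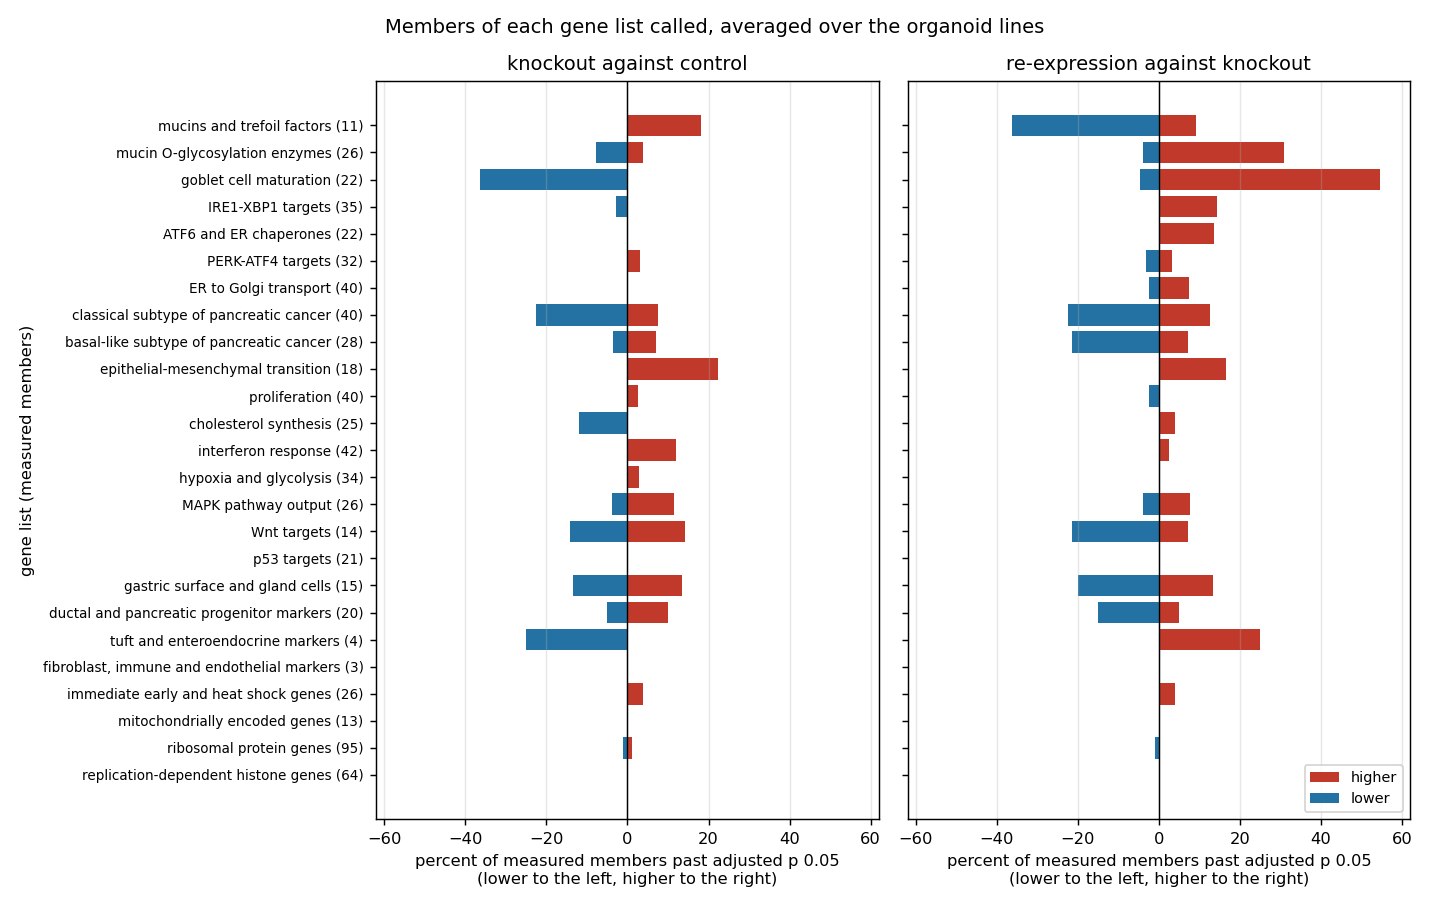
Percent of each gene list's measured members that were higher or lower in the knockout against the control, and in the libraries labelled re-expression against the knockout (edgeR, adjusted p under 0.05). Goblet cell maturation genes show 8 of 22 falling in the first and 12 of 22 rising in the second.

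Genes changed in opposite directions by the 2 manipulations numbered 200, of which 51 fell with the knockout and rose in the libraries labelled re-expression and 149 did the reverse. Among the former were Agr2, Ern2, Creb3l1, Gramd1b, Trf and the sulfotransferase gene Sult1d1, along with Gas6, which encodes a ligand of receptor tyrosine kinases, and Galnt6, whose knockout fall was seen in mT69a and not in mT6. Among the latter were Lgr6, a stem cell receptor gene of the R-spondin family, with log2 fold changes of 3.13 ± 0.32 and -3.05 ± 0.33, and Ltf (lactoferrin), with 2.98 ± 0.55 and -2.88 ± 0.53. Gas6 fell 22.3- and 3.19-fold and rose 111- and 9.12-fold (mT6 and mT69a). Sult1d1 fell 6.15-fold (1.87 to 31.9) and 32.6-fold and rose 20.4-fold (6.39 to 104) and 23.8-fold. Gas6 and Ltf lost the knockout call in 7 and 4 of 12 fits (up to 0.117 without the first mT69a knockout and 0.0782 without the first mT69a control), and Sult1d1 without the second mT6 control (0.416). In the other comparison Trf lost its call in 5 fits (up to 0.101 without the first mT69a re-expression library) and Ltf in 4 (up to 0.0745 without the second mT6 one).

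Both comparisons share the knockout libraries, which alone produce opposite estimates. Independent lists of the same sizes would share 14.8 and 15.8 genes. Across genes the covariance of the log2 fold changes was -0.119, against -0.0659 in 20 simulations with no effect, while the correlation was -0.253 against -0.488 and so nearer to 0 than with no effect. With the knockout libraries divided so that each comparison used different ones, 63 and 61 opposite genes were found (6.72 and 4.83 for independent lists), or 155 and 156 under the block, though each arm then held 1 knockout library per line. In the same fits 30 and 21 genes changed in the same direction, or 76 and 55 under the block. Divided so, without the block, the correlations were 0.00921 and -0.117 and the covariances 0.00618 and -0.0687. The simulations with no effect gave 0 opposite calls, but drew each library independently, without the pairing by replicate number. How many of the 200 arise from the shared libraries stays open. Another 68 genes changed in the same direction in both comparisons. The replicate block gave 548 opposite genes. Leaving out single libraries gave 102 (first mT69a knockout), 117 (first mT6 knockout), 118 and 129 (first or second mT69a re-expression) and 133 (second mT69a control).

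Libraries labelled re-expression were then compared with the controls, to place them against organoids with intact Spdef. Agr2 differed by -0.07 ± 0.39 on the log2 scale (adjusted p = 0.946), with its mean CPM above the control in mT6 and below it in mT69a. Creb3l4 lay above the controls by 5.49 ± 0.13, Creb3l1 by 3.31 ± 0.18 and Ern2 by 2.01 ± 0.28 (adjusted p = 1.08e-08, 3.19e-06 and 0.00127). The kinesin gene Kif26a was 95.1-fold higher in mT6 (36.4 to 354) and 236-fold in mT69a (64.9 to 1953), and the homeobox gene Msx1 30.4-fold and at least 37.5-fold. Gkn3, Psors1c2 and Adamtsl3 were higher 111-fold (29.8 to 929), 32.8-fold and at least 5.62-fold in mT6, and 184-fold (50.5 to 1524), 582-fold (104 to 23026) and at least 40.5-fold in mT69a. Among the largest falls, the water channel gene Aqp1 was 333-fold (92.1 to 2753) and 4.36-fold lower, Fbln1 fell by 4.0 on the log2 scale (SE 0.31), and Cdhr2, of the brush border, was 8.10-fold (2.10 to 69.2) and 91.5-fold lower. Cachd1 and Pnp2 were at least 2.49- and 8.72-fold lower in mT6, and 104-fold (28.4 to 861) and 4.05-fold lower in mT69a. Median log2 fold changes of the knockout in mT6 were -0.37 for chromosome 14, where Pnp2 lies, and -0.44 for chromosome 17, where Psors1c2, Tff1 and Tff2 lie.

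Of 26 O-glycosylation enzymes 10 were higher and 1 lower than in the controls (10 and 3 adjusted over the list alone; camera adjusted p = 0.000171; adjusted p = 0.457 with an estimated correlation), Galnt12 by 2.94 ± 0.15. Of 22 goblet genes 9 were higher and 3 lower (12 and 5 adjusted over the list alone; camera adjusted p = 0.000663; adjusted p = 0.820 with an estimated correlation), the chloride channel regulator gene Clca1 falling by 2.62 on the log2 scale. Of 40 classical markers 16 were lower and 5 higher (17 and 5 adjusted over the list alone; camera adjusted p = 0.00773; adjusted p = 0.651 with an estimated correlation), Hnf4a falling by 1.89. Of 18 genes of epithelial-mesenchymal transition 5 were higher and 1 lower (9 and 3 adjusted over the list alone; camera adjusted p = 0.00773; adjusted p = 0.710 with an estimated correlation), a list that missed the threshold on log2(TPM + 1) and log2(TPM + 0.1) (0.170 and 0.139). Of 42 interferon genes 7 were higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.000856; adjusted p = 0.901 with an estimated correlation). Of 14 Wnt targets 3 were higher and 5 lower (3 and 6 adjusted over the list alone; camera adjusted p = 0.268), Lgr5 and Ascl2 with log2 fold changes of -2.57 ± 0.25 and -2.55 ± 0.43. Camera also gave falls for histone genes, 3 of 64 lower (adjusted p = 1.36e-06), and for ribosomal protein genes and kinases, 7 of 95 (9.89e-05). Adjusted over the lists alone, 0 and 4 were lower. With an estimated correlation both lists had an adjusted p of 0.901. In all 1164 genes were higher and 928 lower, or 3677 under the block, and 183 of the 2092 had a group at 3 counts or fewer. Without the first or second mT69a re-expression library 1208 and 1271 passed.

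Each line was also read within the fit of all 12 libraries, 2 libraries against 2, with the spread shared by the 6 groups. In the mT6 knockout the neurokinin receptor gene Tacr3 rose 155-fold (83.8 to 323; adjusted p = 2.46e-06), the interleukin 5 receptor gene Il5ra 11.96-fold and Naip1, an inflammasome gene with near-identical copies, 9.40-fold. The neuronal scaffold gene Ppp1r9a fell from 486 counts to 0, at least 125-fold, Fam174b at least 48.2-fold and the Wnt receptor gene Ror2 171-fold (30.5 to 6804). In the mT69a knockout Ppic, the nuclear receptor gene Nr2f1 and Ppp2r2c had 0 counts in the controls and rose at least 71.1-, 68.3- and 58.8-fold. Nrn1, a neuritin gene, fell from 107 ± 7.68 to 1.23 ± 0.598 CPM, 94.3-fold (67.4 to 136; adjusted p = 5.61e-07), with Cachd1 and Ern2 next. Gata6, a regulator of the classical subtype, had 0 counts in all mT6 libraries and fell 7.97-fold (4.36 to 16.0) in the mT69a knockout (adjusted p = 0.0216). Genes of chromosome 18, where Ppic and Gata6 lie, had a median of -0.49 there.

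Knockout and control differed in 468 genes in mT6 (185 higher, 283 lower, and 16 with a group at 3 counts or fewer) and 1244 in mT69a (707, 537 and 124). The block gave 1809 and 2320. Fitted with only the groups compared, far fewer genes passed in mT6, as given in the section on processing. On log2(TPM + 1) without a filter the mT6 split was 29 against 70, and on log2(TPM + 0.1) the mT69a split was 299 against 142. In mT6 the number fell to 212 and 170 without the first or second control, 149 and 136 without the first or second knockout, and 279 and 281 without the first or second mT69a re-expression library. In mT69a it fell to 660 and 585 without the first or second control and 548 and 698 without the first or second knockout. Fam174b lost its call in 4 of 12 fits (up to 0.121 without the second mT6 control). The lines shared 41 genes that rose (9.04 for independent lists) and 29 that fell (10.5), while 50 fell in mT6 and rose in mT69a (13.8) and 15 did the reverse (6.86). Across all genes the log2 fold changes of the lines had a Pearson correlation of 0.00614 and a Spearman correlation of 0.0051, genes not being independent replicates.

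The test of the difference between the lines found 958 genes, 585 with a higher and 373 with a lower response in mT69a. Nrn1 rose 2.29-fold in mT6 and fell in mT69a (adjusted p of the difference 1.38e-06), and Ppic fell 5.99-fold in mT6 (3.81e-06). Ckap4, a reticulum membrane protein gene, was 1.02-fold lower in mT6 and 12.7-fold higher in mT69a (4.98e-06), and Stra6, the retinol transporter gene, 1.80-fold lower and 26.3-fold higher (5.84e-06). Epsti1, an interferon-induced gene, was 23.5-fold lower and 34.8-fold higher (1.86e-05). It lies on chromosome 14, whose genes had a median of -0.37 in mT6. Interferon response genes rose in mT69a, 22 of 42 with a median of 3.65, whereas 1 fell in mT6 with a median of -0.16, and 9 members differed between the lines. Of 18 genes of epithelial-mesenchymal transition 9 rose and 1 fell in mT69a and 2 rose and 2 fell in mT6, with 10 differing. Of 40 classical markers 17 fell and 1 rose in mT69a and 2 fell in mT6, with 10 differing. The mT69a numbers depend on single libraries. The 22 interferon genes fell to 6 without the first mT69a knockout, where the median was 1.02, to 2 without either mT69a control and to 11 to 13 without any 1 library of the other groups, and rose to 33 without the second mT69a knockout (42 or 45 members measured). The 9 differing members were 1 to 8 in those fits, apart from 31 without the second mT69a knockout. The 9 rising genes of epithelial-mesenchymal transition fell to 2 without the first mT69a control or knockout, 3 without the second of either and 5 without either mT69a re-expression library. The 10 differing genes of that list fell to 6 without the first mT69a knockout or the second mT69a control. The 17 classical markers fell to 9 without the first mT69a knockout and 11 without the second mT69a control or knockout. The 10 differing ones fell to 5 without the first mT69a knockout or the second mT69a control, and to 6 without either mT6 control or the second knockout of either line. The block gave 2206 differing genes, and log2(TPM + 0.1) a split of 197 against 77. The number fell to 634 and 533 without the first or second mT69a control, 538 and 616 without the first or second mT69a knockout, and 589 without the second mT6 knockout. Of the 958, 91 had a group at 3 counts or fewer.

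**Figure D3:**
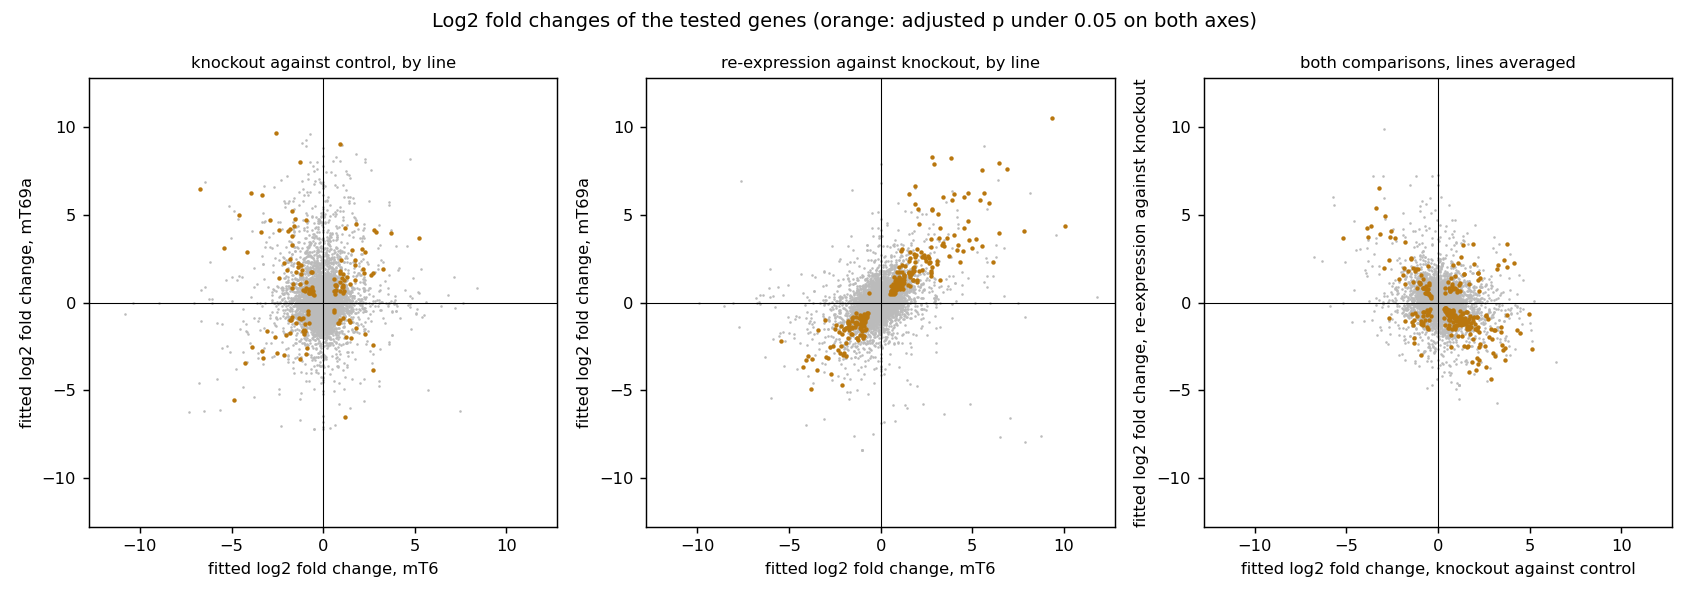
Log2 fold changes of each tested gene: the knockout effect in mT69a against mT6, the effect labelled re-expression in mT69a against mT6, and the averaged re-expression effect against the averaged knockout effect. The correlation across genes between the lines was 0.00614 for the knockout and 0.431 for re-expression.

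**Figure D4:**
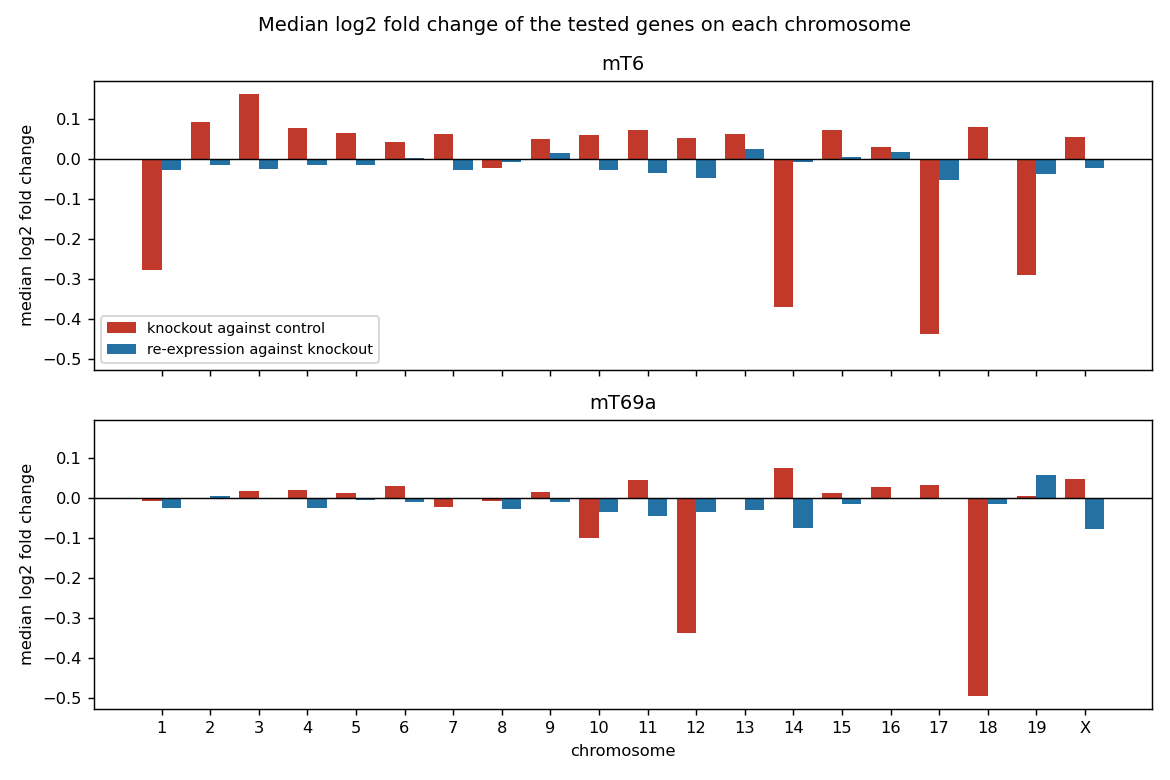
Median log2 fold change of the tested genes on each chromosome, by line, for the knockout against the control and for the libraries labelled re-expression against the knockout. Chromosome 17 shows -0.44 in mT6 and chromosome 18 shows -0.49 in mT69a for the knockout.

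Between the libraries labelled re-expression and the knockout, the lines moved together. Goblet genes rose in each, 9 of 22 in mT6 and 12 of 22 in mT69a with 1 falling in each, and O-glycosylation enzymes rose 6 of 26 in each. Slc12a8, Lman1l and Gkn3 led the mT6 rises and Gkn3, Adamtsl3 and the zinc finger gene Zfp467 (391-fold, 69.7 to 15489) those of mT69a. Fbxw19 fell at least 13.7-fold, Adgrg7 47.5-fold and Nox1, a superoxide-generating oxidase gene, 39.0-fold in mT6, and Gsdmc2, Ppbp and Lypd2 were the largest falls in mT69a. Without the second mT6 knockout library Lman1l (0.0601) and Fbxw19 (0.181) missed the threshold in mT6, Fbxw19 in 10 of 12 fits. Nox1 did so in 3 fits, without the first mT6 knockout or either mT6 re-expression library (up to 0.122 without the second of these). In mT69a Adamtsl3 was lost without the second re-expression or the first knockout library (up to 0.0623), Lypd2 without the first re-expression or the second knockout library (up to 0.169) and Gsdmc2 without the first re-expression library (0.0514).

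In mT6 224 genes were higher and 165 lower (14 with a group at 3 counts or fewer), and in mT69a 372 and 243 (34). The block gave 1055 and 1533. Fitted with only the groups compared, far fewer genes passed in mT6 and more in mT69a, as given in the section on processing. Both lines shared 167 rises (5.76 for independent lists) and 91 falls (2.77). No gene rose in mT6 and fell in mT69a (3.76 for independent lists) and 1 did the reverse (4.24), by edgeR alone, with 1831 and 2210 genes at an unadjusted p under 0.05 in the lines. The correlation across genes was 0.431 (Spearman 0.411). In mT6 the number fell to 181 and 170 without the first or second knockout and 195 without the second re-expression library. In mT69a it fell to 276 and 269 without the first or second knockout and 215 and 282 without the first or second re-expression library. The difference between the lines passed edgeR's test for 2 genes, each with a higher response in mT69a, and none lower, with 712 genes at an unadjusted p under 0.05. DESeq2 called 43 and the block 55. Nectin1, a cell adhesion gene, rose 2.98-fold in mT6 and 74.0-fold in mT69a (adjusted p = 0.00824). The antisense gene Gm27177, named after its values were seen since the naming rule leaves out such genes, differed by 3.83 ± 0.41 (adjusted p = 0.0191). Ltbp1, Gcnt3, Gprc5b and Gnai1 came next and did not pass (0.0556, 0.0556, 0.0707 and 0.0777), but did under the block (0.00211, 0.000663, 0.00656 and 0.0116). The number was 0 without the first or second mT69a knockout or the second mT69a re-expression library, 1 without the first mT69a re-expression, second mT6 knockout or second mT6 re-expression library, and 4 without any 1 control library. Nectin1 itself was lost in 3 of those fits (up to 0.102 without the first mT69a knockout).

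The control organoids of the lines differed in 4078 genes, 1944 higher and 2134 lower in mT69a, 434 of them with a group at 3 counts or fewer. Xist, transcribed from the inactive X chromosome, had 1224 CPM in the mT69a controls and 0.13 in those of mT6. Ugt2b35, of glucuronidation, and the exchange factor gene Rasgrf2 had 21.2 and 16.8 CPM in mT69a and 0 in mT6. The Wnt transcription factor gene Lef1, the stem cell marker Olfm4 and Col4a6 had 23.7, 113 and 19.5 CPM in mT6 and 0, 0.031 and 0 in mT69a. Adjusted p ranged from 1.63e-07 for Xist to 0.000721 for Lef1. On log2(TPM + 1) without a filter the split was 473 against 832. Without the first mT69a control 2040 passed, and without the second mT6 control 2632.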

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

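The tests of copy number as the whole cause, of SPDEF acting differently and of lasting clone differences, and both tests on the Spdef counts, were chosen only after the result was seen. The response to Spdef knockout differed between mT6 and mT69a for 958 genes and the response labelled re-expression for 2, each by edgeR's test of the difference with Benjamini-Hochberg adjustment. Among genes named for the smallest adjusted p of the difference, it was 1.38e-06 for Nrn1, 3.81e-06 for Ppic, 4.98e-06 for Ckap4, 5.84e-06 for Stra6 and 1.86e-05 for Epsti1. Among genes named on other grounds the values were 5.63e-05 for Tacr3, 6.27e-05 for Nr2f1, 0.000109 for Gnai1, 0.000681 for Lipo3, 0.00312 for Il5ra, 0.00470 for Runx3, 0.00602 for Ppp2r2c, 0.0182 for Naip1, 0.0255 for Ifi204, 0.0325 for Lgr6, 0.0397 for Igfbp3 and 0.0422 for Ern2. Nectin1, also named for its adjusted p, had 0.00824 for re-expression.

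Members of the mucin, goblet and subtype lists differed too. The adjusted p were 2.62e-05 for Muc20, 0.00356 for Galnt6, 0.0145 for Gcnt3, 0.000371 for Rap1gap and 0.0124 for Atp10b, and 0.00976 for the transport gene Sec16b. Matrix and interferon genes had 3.35e-05 (Timp3), 0.00179 (Col4a1), 0.00517 (Col4a2), 0.00251 (Tap1) and 0.0119 (Parp14). The rest were Spp1 (0.00255), Hspb1 (0.00400), Notum (0.00582), Car2 (0.00634), Vsig1 (0.00873), Tspan8 (0.0185), Spry2 (0.0357) and Rps6ka2 (0.00212).

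Of the 958 genes 789, or 82.4%, had estimates of opposite sign in the lines, however small. The 958 were selected for a difference, which favours this. Past the threshold in both lines, 50 genes fell in mT6 and rose in mT69a, and 15 did the reverse. Thinning every library to the lowest total left 836 differing genes (808 to 852 in 5 draws), which argues against depth. Copy number as the whole cause is argued against by the 59.0% of the 958 (565) that lie outside the 6 shifted chromosomes, where 76.0% of all tested genes lie. The median share of the difference undone in the libraries labelled re-expression was 0.114 (quartiles -0.068 and 0.299). This cannot decide whether SPDEF acts differently in the lines. All knockout calls were undone as little, with a median share of 0.133 in mT6 and 0.137 in mT69a. The knockout libraries enter both changes with opposite sign, so their noise alone tends to raise these shares. Whether shares this small reflect any reversal stays open. Differences between clones that the vector does not undo and a lasting effect of the loss cannot be told apart, as each line had 1 knockout clone. That 89.2% kept at least 50% of the difference against the controls restates these shares and decides nothing.

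In the knockout, genes of whole chromosomes shifted together in 1 line: chromosomes 1, 14, 17 and 19 in mT6, with medians of -0.28, -0.37, -0.44 and -0.29, and chromosomes 12 and 18 in mT69a, with -0.34 and -0.49. A median beyond 0.25 on either side counted as shifted. None of 10000 random gene lists of the same sizes had so low a median. Smaller shifts within that limit went both ways, chromosome 10 in mT69a with -0.10 (-0.13 in re-expression against control) lying below every random list and chromosome 3 in mT6 with 0.16 (0.16) above all of them. Chromosomes 2, 4, 5, 7 and 11 in mT6, with 0.06 to 0.09, also lay above all random lists. So did 11 and 14 in mT69a, with 0.05 and 0.08. Lying outside the random lists thus does not by itself set the shifted chromosomes apart. GC content and transcript length are argued against by the share of its median that a shifted chromosome kept after correction, 0.948 at least, and the replicate numbers by a share of 0.89 at least in either number. A break at Spdef that lowered only the genes beyond it is argued against by the genes of chromosome 17 before it. These had -0.435 (220 genes), where those beyond had -0.436 (470 genes). Equal medians cannot decide whether the cut led to loss of the whole chromosome. Lower copy number in the knockout clones may be the source, since at least 0.973 of each median was kept in re-expression against control, but DNA was not measured and a gain in the control clones stays open.

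Mouse Spdef stayed at the floor in the libraries labelled re-expression. Knockout libraries under that label are argued against by the 167 genes that rose in both lines, where independent lists would share 5.76. An unmodified mouse sequence at the level of the mT6 controls is argued against by the highest value of those libraries with 3 counts added, 0.467 CPM, against a mean of 1.66. A vector sequence that does not align to the mouse gene, such as a human or recoded one, may explain it and was not tested.

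With line as a term and the difference between lines not fitted, 34 of the 35 splits of each 8 libraries into 4 and 4 could be fitted. The real split alone reached its own count in each comparison, 1 of 34. Since the replicate numbers pair the libraries, it compares with the 7 other splits that part all 4 pairs, which are too few for a share under 0.05. Knockout against control gave 108 genes and at most 91 in another split, the one with the conditions of mT69a exchanged, which points to effects that differ between the lines. Re-expression against knockout gave 1097, and at most 52, in the split by replicate number. Re-expression against control gave 872, and at most 33, again with mT69a exchanged. Those 7 splits gave at most 91, 0 and 33 genes by edgeR.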

How the results depend on the processing

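The fits without mitochondrial and ribosomal RNA genes and of either replicate number alone were chosen only after the result was seen. Numbers of genes follow this order unless named: knockout, re-expression against knockout, re-expression against control, knockout in mT6 and in mT69a, re-expression in mT6 and in mT69a, difference in knockout and in re-expression between lines, controls of the lines, and opposite changes. DESeq2's size factors and leaving out mitochondrial and ribosomal RNA genes moved no number by over 1.5 times. Without a count filter, which adds genes, there were 1555 (knockout), 1740 (re-expression), 1089 and 950 (knockout and re-expression in mT6), 1175 (re-expression in mT69a), 1577 and 196 (differences) and 434 (opposite). DESeq2's Wald test gave 43 for the difference in re-expression. Limma on log2(TPM + 1) gave 285, 447, 758, 97, 412, 165, 225 and 289, then 1278 for the controls and 75 opposite. On log2(TPM + 0.1) there were 285, 421, 749, 92, 441, 144, 202, 274, 1, 1322 and 73, and without a filter on TPM 302, 420, 728, 99, 477, 146, 217, 239, 27, 1305 and 77. The replicate block gave 2171, 2293, 3677, 1809, 2320, 1055, 1533, 2206 and 55, with 548 opposite, and the block within each line 2825, 2812, 4241, 2521, 2823, 1473, 2098, 2831 and 126, with 759 opposite. With only the groups compared, and so with fewer libraries, there were 13 and 26 for knockout and re-expression in mT6 and 1102 for re-expression in mT69a. Either replicate number alone gave 0 for the averaged comparisons and opposite changes by edgeR, the only tool run there, with 1 library per group and 1010, 1242 and 1825 genes (number 1) and 790, 1158 and 1632 (number 2) at an unadjusted p under 0.05. Leaving out 1 library gave 431 to 889, 637 to 1098, 1208 to 1904, 136 to 499, 548 to 1316, 170 to 368, 215 to 712, 533 to 1064, 0 to 4, 2040 to 4354 and 102 to 207, a lone library being assumed to vary like the other groups. Named genes stayed on their side of the threshold in 2946 cases, went past it in 139, fell short in 674 and reversed in 2, and in 3611, 25, 372 and none with 1 library left out. A change of sign counted as a reversal only where a gene or list passed in either of the fits compared. Those that passed in neither could change sign uncounted, as Spdef did in re-expression against knockout (0.02, and -0.05 under the block). The reversals were Muc20 in the knockout, -0.02 and -0.26 in replicate number 1 and 2 alone, in fits that weight the lines by their counts. Lists kept their call in 678 cases, gained it in 17 and lost it in 38, 21 of them with the estimated correlation. The others were epithelial-mesenchymal transition in the knockout (0.0823 on log2(TPM + 1), 0.0604 on log2(TPM + 0.1) and 0.0694 without a filter on TPM) and in re-expression against control (0.170 and 0.139 in the first pair of these). For re-expression against knockout they were, in the same order, ATF6 (0.0563, 0.0604 and 0.138), transport (0.0563, 0.0604 and 0.112) and basal-like genes (0.138, 0.152 and 0.0616), with ATF6 also lost without a count filter (0.0748), IRE1-XBP1 without a filter on TPM (0.0856) and proliferation on log2(TPM + 0.1) (0.0597). Gained in re-expression against knockout were cholesterol and histone genes without a count filter (0.0497 and 0.0264), Wnt targets in the 3 fits on TPM (0.00692, 0.00685 and 0.0186), histone genes without a filter on TPM (0.0297), and mitochondrial genes in the first pair of TPM fits (0.0226 and 0.0276) and under the block and the block within lines (0.00234 and 0.00108). Gained in re-expression against control were proliferation, cholesterol and Wnt targets without a count filter (0.00103, 0.00162 and 0.0479), Wnt targets on log2(TPM + 1) and log2(TPM + 0.1) (0.0184 and 0.0226), gastric genes on log2(TPM + 0.1) (0.0496) and cholesterol without a filter on TPM (0.0297). With 1 library left out these were 857, 34 and 7, and 2 reversed: hypoxia (direction -1 without the first mT6 re-expression library, adjusted p 0.0414) and interferon (direction 1 without the first mT69a knockout, 5.80e-06), both for re-expression against knockout. Of the 34 gained, those in the knockout were hypoxia, MAPK and immediate early genes without the first mT6 control (0.0273, 0.0477 and 0.0382), hypoxia without the second mT6 or mT69a knockout (0.0429 and 0.00261) and proliferation without the first mT69a control (0.00653). In re-expression against knockout they were mitochondrial (lowest 0.00122), histone (lowest 6.93e-06), PERK-ATF4 (lowest 0.0222), cholesterol (0.0229), MAPK (0.0268), immediate early (0.00976) and interferon genes (6.75e-09). In re-expression against control they were cholesterol, MAPK and immediate early genes without the first mT6 control (0.0280, 0.00764 and 0.0231) or the second mT6 re-expression library (0.00516, 0.00278 and 0.00510), and hypoxia without the latter (0.00821). IRE1-XBP1, ATF6, transport and mitochondrial genes were gained there without the first mT6 re-expression library (0.000551, 0.00174, 0.0431 and 0.0342), IRE1-XBP1 and proliferation without the second mT69a control (0.0322 and 0.000565), proliferation without the first mT69a re-expression library (0.0455) and MAPK without the second (0.0494). Apart from the added genes, the cause of these changes was not tested. Depth limits genes near 3 counts in a group, Spdef in mT69a among them.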

Other observations

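In the knockout, 1 of 40 proliferation genes rose (Cenpe, by 0.59 ± 0.10; 1 adjusted over the list alone; camera adjusted p = 0.450), and in the libraries labelled re-expression Rrm2 fell by 0.59 on the log2 scale (1 adjusted over the list alone; camera adjusted p = 0.00546; adjusted p = 0.901 with an estimated correlation). The block gave 2 higher and 1 lower in the knockout and 1 and 7 in re-expression. The list passed in the knockout without the first mT69a control (0.00653). In re-expression the list missed the threshold without the second mT69a knockout (0.0517), and Rrm2 without the second mT69a re-expression library (0.0702). Of 25 cholesterol synthesis genes 3 fell in the knockout (4 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.381), among them Tm7sf2 and Stard4, lost in 10 of 12 fits each (up to 0.144 without the second mT69a knockout and 0.184 without the first). In re-expression 1 rose (camera adjusted p = 0.381). No member passed over the list alone in edgeR, with 9 at an unadjusted p under 0.05 and 3 in DESeq2. The block gave 2 higher and 5 lower in the knockout and 4 and 4 in re-expression, where the list passed without the second mT6 re-expression library (0.0229). Of 32 PERK-ATF4 targets Slc7a5 rose and Stc2 fell in re-expression (1 and 1 adjusted over the list alone; camera adjusted p = 0.381), lost in 4 and 8 fits (up to 0.0912 and 0.136 without the first mT69a re-expression library). The list passed without the second mT6 knockout (0.0455) or the second mT69a knockout (0.0222).

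Of 34 hypoxia and glycolysis genes P4ha2 rose in the knockout by 0.72 (1 adjusted over the list alone; camera adjusted p = 0.268), lost in 3 fits (up to 0.0703 without the first mT69a knockout), and the list passed without the first mT6 control (0.0273) or the second mT6 or mT69a knockout (0.0429 and 0.00261). No member passed in re-expression (edgeR, 6 at an unadjusted p under 0.05, 2 in DESeq2; camera adjusted p = 0.989), where the replicate block gave 1 higher and 4 lower, though the list turned downward without the first mT6 re-expression library (0.0414). Of 26 MAPK output genes 3 rose and 1 fell in the knockout (3 and 2 adjusted over the list alone; camera adjusted p = 0.381), Emp1 by 1.21 ± 0.12, Ereg lost in 7 fits and Spry2 in 6 (up to 0.133 without the first mT69a knockout and 0.153 without the first mT69a control). The list passed in the knockout without the first mT6 control (0.0477) and in re-expression without the second mT6 re-expression library (0.0268). In re-expression 2 rose, among them Spred3 by 2.03, and Emp1 fell by 0.83 (2 and 1 adjusted over the list alone; camera adjusted p = 0.381). Of 14 Wnt targets 2 rose and 2 fell in the knockout (2 and 3 adjusted over the list alone; camera adjusted p = 0.406), Notum by 1.15 and Lgr5 by -1.45, and 1 rose and 3 fell in re-expression (1 and 5 adjusted over the list alone; camera adjusted p = 0.206, but 0.00692 on log2(TPM + 1), 0.00685 on log2(TPM + 0.1) and 0.0186 without a filter on TPM). No p53 target of 21 passed in either by edgeR (0 and 3 at an unadjusted p under 0.05, 0 in DESeq2; 0 and 2 lower under the block; camera adjusted p = 0.272 and 0.774).

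Of 15 gastric genes 2 rose and 2 fell in the knockout (2 and 2 adjusted over the list alone; camera adjusted p = 0.406), Lgals2 by -2.25 and Vsig1 by -2.11, and 2 rose and 3 fell in re-expression (2 and 3 adjusted over the list alone; camera adjusted p = 0.381). Of 20 ductal and progenitor markers 2 rose and 1 fell in the knockout (4 and 1 adjusted over the list alone; camera adjusted p = 0.374), Spp1 by 2.24, Car2 by 1.35 (lost in 3 fits, up to 0.0715 without the second mT6 knockout) and Tspan8 by -0.60 (lost without the first mT69a knockout, 0.0614). In re-expression 1 rose and 3 fell (2 and 3 adjusted over the list alone), camera upward (adjusted p = 0.514) with a median of 0.10 and a mean of -0.10. Of 4 tuft and enteroendocrine markers Avil fell in the knockout (1 adjusted over the list alone; camera adjusted p = 0.406), lost in 6 fits (up to 0.0981 without the second mT6 knockout). Pcsk1n rose in re-expression (1 adjusted over the list alone), lost in 6 fits (up to 0.183 without the first mT69a re-expression library), camera upward (adjusted p = 0.949) with a median of -0.31 and a mean of 0.26.

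Of 26 immediate early and heat shock genes Hspb1 rose in the knockout by 0.88 (1 adjusted over the list alone; camera adjusted p = 0.424), lost in 5 fits (up to 0.0853 without the first mT69a knockout), and Nr4a1 in re-expression by 2.48 ± 0.16 (1 adjusted over the list alone; camera adjusted p = 0.440). The list passed in the knockout without the first mT6 control (0.0382) and in re-expression without the second mT6 re-expression library (0.00976). No mitochondrially encoded gene of 13 passed in either (edgeR, 1 and 1 at an unadjusted p under 0.05, 0 in DESeq2; camera adjusted p = 0.461 and 0.113), and the replicate block gave 1 lower in the knockout and 4 higher in re-expression (camera adjusted p = 0.00234). That list also passed in re-expression on log2(TPM + 1) and log2(TPM + 0.1) (0.0226 and 0.0276), without the first mT6 or mT69a re-expression library (0.00122 and 0.0148) and without the second mT6 or mT69a knockout (0.00197 and 0.00711). Of 95 ribosomal protein genes and kinases Rps6ka2 rose and Rps29 fell in the knockout, the latter lost in 10 fits (up to 0.161 without the first mT69a knockout; 1 rose over the list alone). Camera was downward (adjusted p = 0.696) with a median of 0.02. The block gave 2 higher and 8 lower. In re-expression Rps6ka2 alone fell in edgeR (8 fell under the block), lost in 4 fits (up to 0.0650 without the first mT69a knockout), with camera adjusted p = 1.83e-05, and adjusted p = 0.901 with an estimated correlation. Over the list alone none passed in edgeR, with 5 at an unadjusted p under 0.05 and 2 in DESeq2. Of 64 histone genes none passed in either (edgeR, 5 and 4 at an unadjusted p under 0.05, 0 in DESeq2, 1 lower in each under the block), while camera gave a fall in the knockout (adjusted p = 6.89e-06; adjusted p = 0.901 with an estimated correlation) with a median of -0.23. In re-expression camera gave 0.206, but the list passed without the first mT6 re-expression library (6.93e-06), the first mT69a knockout (0.000250) or the first mT69a re-expression library (0.00991), and without a count filter or a filter on TPM (0.0264 and 0.0297).

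Markers of other cell types were scarce. Of 30 fibroblast, immune and endothelial markers 28 stayed under 1 CPM in every library, 8 of them at 0, and of 27 acinar markers 26 did, 11 of them at 0. The 3 measured of the former passed in neither comparison by edgeR (0 and 2 at an unadjusted p under 0.05, 0 and 1 in DESeq2, none and 2 lower under the block; camera adjusted p = 0.374 and 0.343), with 2 falling in re-expression when adjusted over the list alone. Of the knockout calls in mT6 and mT69a, 55 (11.8%) and 164 (13.2%) were reversed past the threshold in the libraries labelled re-expression, with a median share undone of 0.133 and 0.137. Both comparisons share the knockout libraries, whose noise alone tends to raise these numbers.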
